A study of Mus musculus with 30 samples.

How the data were processed

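Polyadenylated RNA of the whole cerebral cortex was measured by bulk RNA sequencing in 30 libraries, each from 1 mouse, in 6 groups given by the labels (Cre driver and age; controls Brapflox/wt without Cre, the others Brapflox/flox with Cre). The values are estimated counts per gene from Salmon 1.5.2 against the mouse genome build GRCm38, as deposited and per the submitters' processing notes. Between 14.7% and 23.7% of the values in a library were not whole numbers, and all were rounded to whole counts before use. The annotation release, the strand setting and the read numbers before mapping are not given in the sources used here. Of the 54418 gene identifiers, 54096 were found in GENCODE mouse release M21, from which coordinates and gene types were taken.

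Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total count 15), which left 17796. Counts were scaled by TMM, and all 30 libraries were fitted with 1 coefficient per group by edgeR's quasi-likelihood pipeline with robust dispersion (R 4.3.3, edgeR 4.0.16, limma 3.58.1). For each of the 9 comparisons p was adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. Log2 CPM values used a prior count of 2. The change of the effect with age was tested as an interaction contrast.

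A total of 49 gene lists had been written down from general knowledge, and 48 were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists of each comparison. Camera was repeated with an estimated correlation, and fry, a rotation test of whether a list moves in 1 direction, was run beside it. Members were also adjusted over the list alone. Genes named in the text are Brap, the driver genes, the neighbours of Brap, the 10 largest changes in each direction among called genes with a mean of at least 1 CPM, and up to 4 members of smallest adjusted p from each described list. The groups, comparisons, lists, this rule and most alternatives were fixed before the data were examined.

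A gene at 0 in every library of a group was given a fold against a floor of 3 counts over that group, and a gene with 1 to 3 counts a ratio with a 95% counting interval. These floors and intervals cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules. Genes with near-identical copies were found from shared 31-base words in the reference transcripts. Sex was read from Xist and Y-linked genes and used only as a covariate or to restrict the libraries.

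The alternatives were another scaling (RLE), no filter and a stricter filter (at least 1 CPM in at least 4 libraries), DESeq2 1.42.0, limma voom with sample quality weights, a fit of only the groups compared, sex as a covariate, replicate numbers as a block, and leaving out each library in turn. Fits of 1 sex, and fits without replicate 6 of Emx1-Cre at 10 months, were added after the data had been seen. Each comparison was also repeated on up to 100 regroupings of its libraries. The pipeline was tested on simulated data of the same design, with known changes of 1.5-, 2- and 4-fold in 200 genes, once with a shared spread and once with each group's own spread. No library was left out, and no pair of libraries was a duplicate. Replicate numbers showed no steady pairing of libraries across groups: across genes, correlations of the deviations from the group means between libraries of the same number ranged from -0.221 to 0.361. Between Emx1-Cre and control at 10 months they ran from 0.0365 to 0.177. There 2 of 4 Emx1-Cre libraries correlated best with the control of their own number, so pairing at that age cannot be excluded.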

Results

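Polyadenylated RNA of the whole mouse cerebral cortex was sequenced from 30 mice to compare animals carrying a conditional deletion of Brap with controls that lacked Cre recombinase. The labels give the controls as Brapflox/wt without Cre and the other mice as Brapflox/flox with Cre, so that these groups also differ in the number of floxed alleles. Brap encodes an E3 ubiquitin ligase that restrains signalling from RAS to the MAP kinases. Cre was driven by Emx1 in neural progenitors, by Thy1 in postnatal neurons or by Tie2, the gene now named Tek, in vascular endothelium. The title of the series names cell type and age as the questions. At 3 months there were 4 control, 6 Emx1-Cre, 5 Thy1-Cre and 5 Tie2-Cre mice, and at 10 months 4 control and 6 Emx1-Cre mice. The labels call the phenotype strong for Emx1-Cre at 3 months and for Thy1-Cre, mild for Tie2-Cre and recovered for Emx1-Cre at 10 months. The deposited table gave estimated counts for 54418 genes, of which 17796 were tested, and each library held between 21430882 and 28720055 counts. Levels are given below as CPM (counts scaled by TMM to library size, mean ± SD), and changes as log2 fold changes ± standard error (SE).

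The first principal component of the log2 CPM values held 31.3% of the variance. On it the 3-month controls lay at -37.0 ± 4.13 (SD, n = 4), the Tie2-Cre libraries at -31.6 ± 3.75 (n = 5) and the 10-month controls at -38.9 ± 1.88 (n = 4). The libraries labelled Emx1-Cre at 3 months lay at 65.3 ± 33.5 (n = 6) and those labelled Thy1-Cre at 41.2 ± 24.1 (n = 5). Within these groups replicate 6 of Emx1-Cre lay at -1.58 and replicate 2 of Thy1-Cre at 0.605. The Emx1-Cre libraries of 10 months lay at -22.8 ± 14.9 (n = 6), from -45.9 to -1.99. All 5 Thy1-Cre libraries came from females by their Xist and Y-linked counts, while the 3-month controls held 2 females and 2 males.

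Brap itself (ENSMUSG00000029458.14, GRCm38 chromosome 5, 121660563 to 121687256, plus strand, protein-coding) was higher, not lower, in the libraries labelled Emx1-Cre and Thy1-Cre at 3 months, and did not pass the test in the other groups labelled as carrying its deletion. The 3-month controls held 66.5, 59.2, 58.4 and 62.5 CPM of Brap. The libraries labelled Emx1-Cre at 3 months held 93.1, 77.4, 110, 114, 113 and 68.5 CPM, those labelled Thy1-Cre 74.4, 86.5, 90.4, 71.7 and 80.5 CPM, and those labelled Tie2-Cre 68.0, 66.1, 65.6, 71.1 and 59.7 CPM. At 10 months the controls held 63.4, 60.7, 56.6 and 59.2 CPM and the libraries labelled Emx1-Cre 87.1, 89.6, 69.9, 84.7, 80.5 and 63.0 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Brap rose by 0.64 ± 0.12 in the libraries labelled Emx1-Cre at 3 months (adjusted p = 0.000217, higher than all controls in 6 of 6), a call lost in males alone (adjusted p = 0.123). In the same test it rose by 0.39 ± 0.12 in those labelled Thy1-Cre (adjusted p = 0.0268, 5 of 5). That call was lost without replicate 2, 3 or 4 of the controls (adjusted p = 0.0663, 0.0651 and 0.0524), without replicate 3 of Thy1-Cre (0.0559), with sex as a covariate (0.0877) and in females alone (0.0921), all in edgeR's quasi-likelihood test. The changes of 0.10 ± 0.12 with Tie2-Cre and 0.40 ± 0.12 with Emx1-Cre at 10 months did not pass it (adjusted p = 1.00 and 0.251). The counts cover the whole gene, and which exons were floxed is not given in the sources used here, so this value cannot show whether the deletion took place. Since the deletion could not be checked here, every direction below holds for the libraries as labelled.

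**Figure D1:**
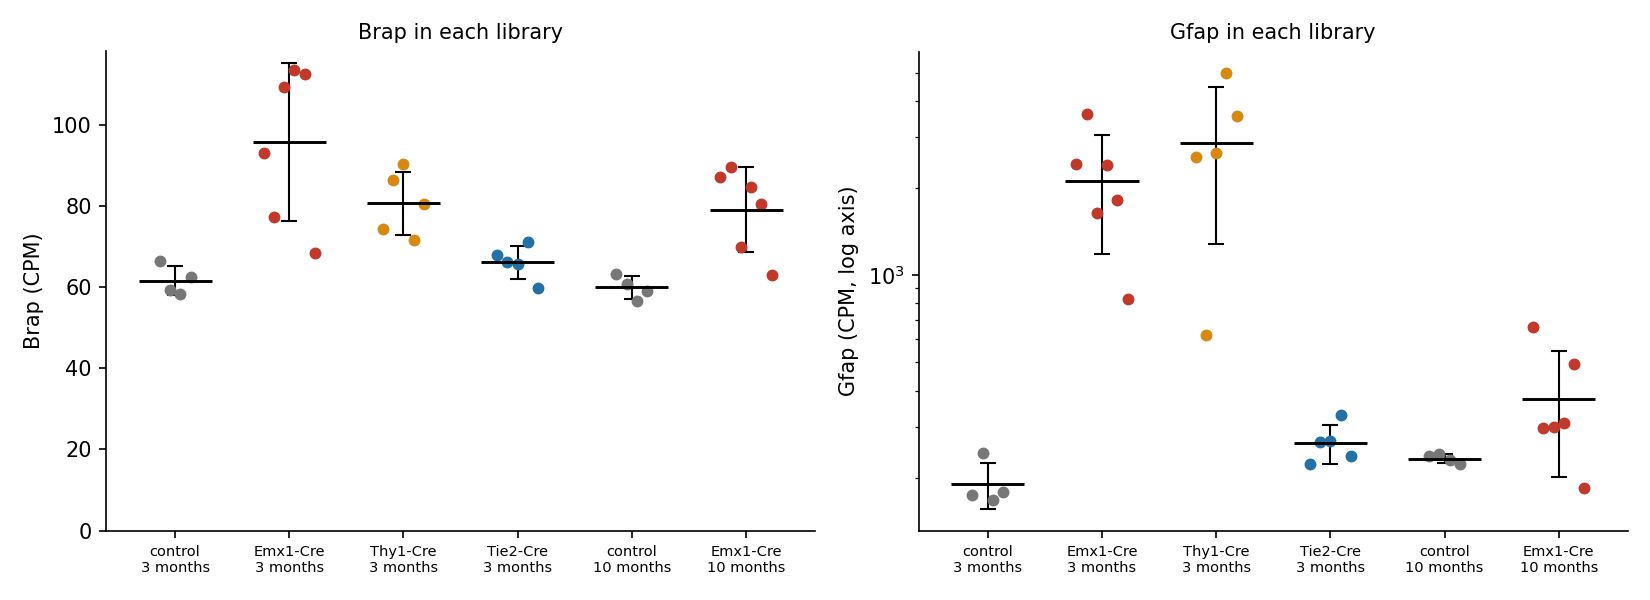
Brap (left, CPM, linear axis from 0) and Gfap (right, CPM, log axis) in each of the 30 libraries, by labelled group. Points are libraries, and bars are group means with SD. Brap ranged from 58.4 to 66.5 CPM in 3-month controls and from 68.5 to 114 CPM in the libraries labelled Emx1-Cre at 3 months. Gfap had means of 191 CPM and 2112 CPM in these groups and 375 CPM in the libraries labelled Emx1-Cre at 10 months.

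The 13 measured neighbours of Brap on chromosome 5 showed no common direction. In the libraries labelled Emx1-Cre at 3 months 5 of them rose, led by Trafd1 with 0.87 ± 0.20, and Tmem116 fell by 0.84 ± 0.25 on the log2 scale. Without replicate 3 of the controls or replicate 1 of Emx1-Cre, 3 of the 5 still passed the test. The call of Tmem116 was lost on the 10 libraries of this comparison alone (adjusted p = 0.0674), in females alone (0.165) and in males alone (0.170), and that of Trafd1 in males alone (0.0585), all in edgeR's quasi-likelihood test. The driver genes Emx1 and Thy1 did not pass the test there (0.11 ± 0.21 and -0.26 ± 0.13). Tek, the endothelial angiopoietin receptor, fell from 11.6 ± 2.72 CPM (n = 4) to 5.27 ± 1.34 CPM (n = 6), a call lost in females alone (adjusted p = 0.0741 in edgeR's test).

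The comparison of the libraries labelled Emx1-Cre with controls at 3 months asks what loss of Brap from neural progenitors leaves in the cortex. The list of reactive astrocyte markers rose. Its mean log2 CPM was 2.96 in replicate 6 of Emx1-Cre and 4.84 to 5.46 in the other replicates. Of the 26 measured members of this list, 24 rose and 0 fell, the same counts when adjusted over the list alone. Gfap, the intermediate filament of astrocytes, rose from 191 ± 34.7 CPM (n = 4) to 2112 ± 926 CPM (n = 6), by 3.47 ± 0.44. Timp1, an inhibitor of metalloproteinases, rose by 7.05 ± 1.00, Osmr, the oncostatin M receptor, by 3.60 ± 0.51 and Aspg, an asparaginase, by 2.87 ± 0.30, with adjusted p between 1.3e-06 and 2.1e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each of these 4 genes exceeded every control in 6 of 6 libraries. Timp1, however, stood at 0.816 CPM in replicate 6, against up to 0.247 CPM in controls and 18.8 to 39.1 CPM in the other replicates.

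Several lists of microglial and immune genes rose with them, while class II antigen presentation did not: 0 of its 7 genes rose and 3 fell (2 and 4 when adjusted over the list alone), and its mean log2 CPM was below every control in 4 of 6 libraries. Of 25 markers of disease-associated microglia 23 rose, among them Gpnmb, a lysosomal glycoprotein (3.45 ± 0.50), Itgax, an integrin (3.65 ± 0.55), and Cd68, a phagocyte marker (2.84 ± 0.47). Among 12 complement genes 9 rose, 11 when adjusted over the list alone. C3 rose by 4.81 ± 0.77, C1qa by 2.76 ± 0.47, and C4b, which has a near-identical copy and is uncertain for that reason, from 35.3 ± 15.2 to 203 ± 59.9 CPM. C4b is uncertain also because it varied with the ribosomal protein gene Rps18 within groups, as given below for Tie2-Cre. Interferon-stimulated genes were higher in 27 of 34, and in 30 when adjusted over the list alone, led by the chemokine Cxcl10 (8.25 ± 1.72) and the antiviral Gbp2 and Ifitm3 (3.65 ± 0.74 and 2.56 ± 0.52). These genes varied widely between mice. Their mean log2 CPM was 5.69 in replicate 1 of Emx1-Cre against 1.16 to 2.92 in the other 5, where replicate 6 held 1.16, inside the range of 0.587 to 1.27 in the controls, and Cxcl10 stood at 51.4 ± 112 CPM (n = 6) against 0.164 ± 0.103 CPM (n = 4). Class I antigen presentation rose in 12 of 13 genes, among them the peptide transporter Tap1 (2.70 ± 0.62). The 22 lysosomal genes split into 19 higher and 1 lower, with cathepsins Ctsd and Ctsl up by 2.08 ± 0.36 and 1.63 ± 0.29. Among 18 markers of homeostatic microglia 5 rose and 0 fell, including the Fc receptor Fcgr3 (2.21 ± 0.35), but their mean log2 CPM was above the controls (3.90 to 4.28) only in replicates 1 and 2 of Emx1-Cre (4.60 and 5.52), within their range in replicate 6 (4.15) and below it in replicates 3, 4 and 5 (3.72, 3.85 and 3.80).

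Synaptic, upper-layer and myelin genes were lower in the same libraries, while markers of deep-layer neurons (1 of 16 higher, 3 lower) and interneurons (5 of 21 higher, 3 lower) went both ways. Of 33 synaptic genes 18 fell and 0 rose, among them Stx1a, a syntaxin of the release machinery, from 249 ± 21.5 to 113 ± 30.3 CPM, and the glutamate receptor subunit Gria4 (-0.77 ± 0.13). Upper-layer excitatory markers fell in 8 of 12 genes, 9 when adjusted over the list alone, with Lamp5 at -1.71 ± 0.19, Rspo1 at -1.84 ± 0.21 and Otof at -2.21 ± 0.42. Myelin and oligodendrocyte genes fell in 12 of 19, 14 when adjusted over the list alone, with the myelin lipid enzyme Ugt8a at -2.15 ± 0.34 and Ermn at -1.73 ± 0.29. Immediate early genes went both ways: 3 of 21 rose and 8 fell. Arc, an activity-regulated synaptic gene, fell from 368 ± 168 to 29.9 ± 14.6 CPM and Nr4a2 by 1.90 ± 0.32 on the log2 scale, while Jun rose by 1.28 ± 0.25. Neuropeptide genes rose in 11 of 16, with Npy at 2.12 ± 0.39, the granin Scg2 at 1.80 ± 0.36 and Adcyap1 at 2.46 ± 0.51; adjusted over the list alone 11 rose and 1 fell. Their mean log2 CPM was within the control range (4.89 to 5.28) in replicates 1 and 2 of Emx1-Cre (5.21 and 5.12), just above it in replicate 6 (5.36) and at 6.52, 5.74 and 6.95 in replicates 3, 4 and 5. In males alone the list was not called by camera (adjusted p = 0.0874) nor Npy by edgeR (0.106).

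Vascular and stress genes completed the picture. Endothelial activation genes split into 11 higher and 1 lower of 15, with the adhesion molecule Icam1 (3.60 ± 0.44) and endothelin Edn1 (3.19 ± 0.52) up and the ligand Apln down (-2.15 ± 0.39). Basement membrane genes rose in 8 of 16 and fell in 1 (10 and 2 when adjusted over the list alone), led by Sparc (2.13 ± 0.25) and Col4a1 (1.94 ± 0.37). Among 17 p53 targets 9 rose, including the cell cycle inhibitor Cdkn1a (2.77 ± 0.63), and Zmat3 fell by 0.61 ± 0.11 on the log2 scale. Senescence-associated secretory genes rose in 10 of 17 and fell in 1 (11 and 1 when adjusted over the list alone), with Igfbp3 at 2.13 ± 0.40. Proteasome subunits rose in 29 of 31, by small amounts (median 0.49), such as Psmb2 (0.84 ± 0.13) and Psmd3 (0.63 ± 0.10). Nuclear genes of oxidative phosphorylation rose in 18 of 38 (median 0.25), with Sdhb at 0.55 ± 0.10. Cell cycle genes rose in 8 of 18, with Pcna at 0.55 ± 0.14. Glucocorticoid targets rose in 7 of 10, 8 when adjusted over the list alone, with Fkbp5 at 1.82 ± 0.32. Cholesterol synthesis genes fell in 8 of 17, 9 when adjusted over the list alone, with Idi1 at -0.70 ± 0.16.

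Over all genes 3628 were higher and 3396 lower in the libraries labelled Emx1-Cre at 3 months, of which 1337 and 996 differed at least 2-fold. Among the largest changes stood Slc10a6, a transporter of sulfated steroids, at least 216-fold higher (a floor of 3 counts over the control group), and Lcn2, an iron-binding acute-phase protein, at 69.1 ± 40.7 against 0.0727 ± 0.0692 CPM. Rps18 fell by 4.34 ± 0.88 on the log2 scale, but it has near-identical copies and is uncertain. With limma's camera test 19 of 48 lists shifted, from an adjusted p of 1.4e-13 for reactive astrocytes and the proteasome to 0.00995 for cholesterol synthesis. None of the 19 held with an estimated correlation, where adjusted p = 0.410 to 0.727 with an estimated correlation. In females alone the calls of interferon-stimulated, cell cycle and cholesterol synthesis genes were lost (adjusted p = 0.0949, 0.123 and 0.546), and in males alone those of neuropeptide and basement membrane genes (0.0874 and 0.207). Fitted on these 10 libraries alone, edgeR's test called 2054 genes higher and 1855 lower. Among the genes named for this comparison 10 lost their call in females alone (adjusted p = 0.0508 to 0.165) and 7 in males alone (0.0517 to 0.170).

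**Figure D2:**
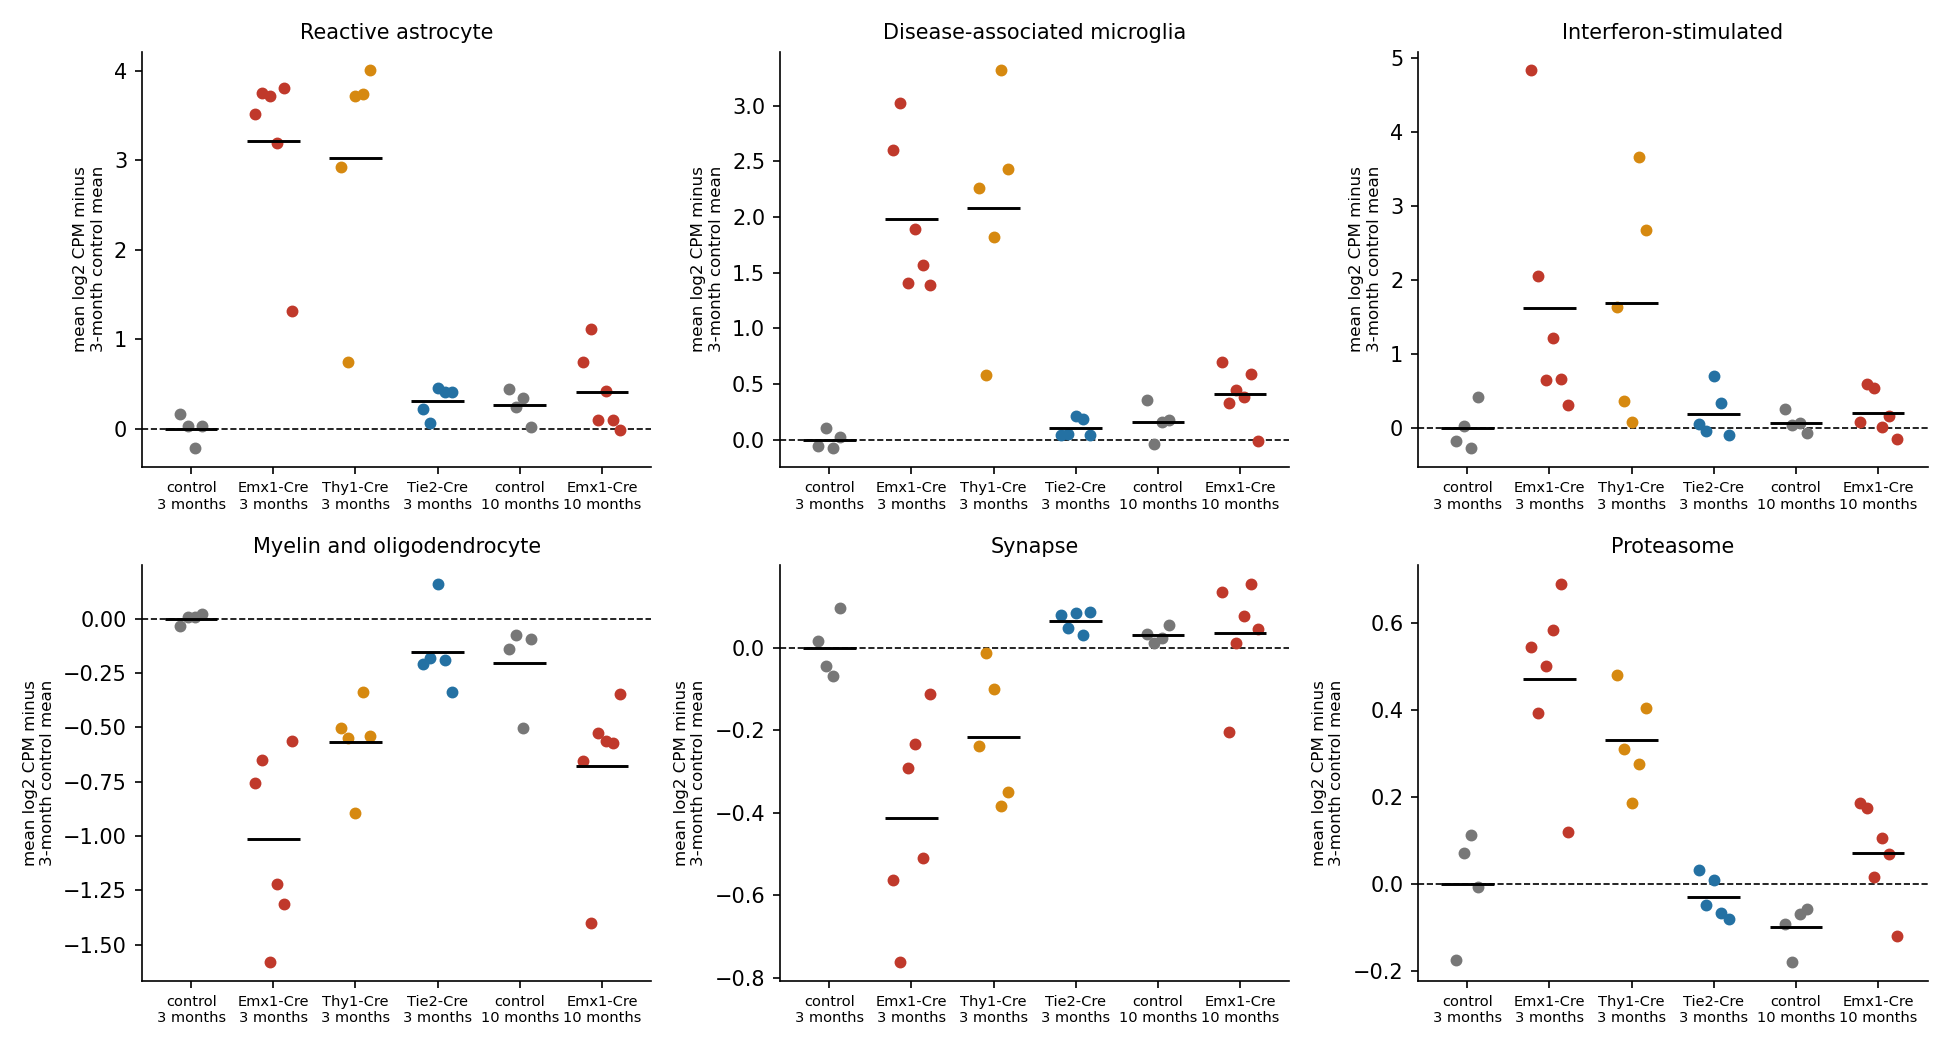
Mean log2 CPM deviation from the 3-month controls of 6 fixed gene lists in each library, by labelled group. Points are libraries, horizontal bars group means and the dashed line the mean of the 3-month controls. The lists shown as reactive astrocyte and disease-associated microglia hold 26 and 25 tested genes, of which 24 and 23 rose in the libraries labelled Emx1-Cre at 3 months.

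The libraries labelled Thy1-Cre, in which Cre acts in postnatal neurons, were compared with the same 3-month controls. Reactive astrocyte genes rose in 23 of 26, and in 25 when adjusted over the list alone. Gfap reached 2866 ± 1585 CPM (n = 5), a rise of 3.91 ± 0.45, and replicate 2 held the lowest value of the group, 621 CPM. Aspg rose by 3.33 ± 0.31, Timp1 by 7.36 ± 1.02 and Cd44, a hyaluronan receptor, by 4.88 ± 0.72, with adjusted p between 2.9e-07 and 9.7e-05 for these 4 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Replicate 2 held 0.923 CPM of Timp1, against up to 0.247 CPM in controls and 20.7 to 53.1 CPM in the other replicates of Thy1-Cre. Disease-associated microglial genes rose in 21 of 25, with Itgax at 4.47 ± 0.57, the chemokine Ccl3 at 5.95 ± 0.93 and the galectin Lgals3 at 4.58 ± 0.76. Complement genes rose in 9 of 12 (11 when adjusted over the list alone), interferon-stimulated genes in 17 of 34 (27 when adjusted over the list alone) and class I antigen presentation in 7 of 13 (8 when adjusted over the list alone). The mean log2 CPM of interferon-stimulated genes was above the controls (0.587 to 1.27) in replicates 1, 4 and 5 of Thy1-Cre (2.49, 4.52 and 3.53) and within their range in replicates 2 and 3 (1.23 and 0.942). C4b, uncertain as above, rose by 2.68 ± 0.31, Ifitm3 by 2.41 ± 0.52 and H2-D1, a class I gene with close family members, by 1.62 ± 0.32.

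Cell cycle genes rose in 13 of 18 in the libraries labelled Thy1-Cre, and in all 18 when adjusted over the list alone. Mki67, a marker of dividing cells, stood at 13.2 ± 14.4 CPM (n = 5) against 1.98 ± 0.559 CPM (n = 4), with Aurkb up by 2.86 ± 0.76 and Pcna by 0.62 ± 0.15; the mean log2 CPM of the list was 3.11 and 3.34 in replicates 1 and 4 and 0.316 to 1.04 in the other 3, against 0.281 to 0.720 in controls. On the 9 libraries alone Mki67 and Aurkb had adjusted p = 0.0776 and 0.0670 in edgeR's test. Proteasome subunits rose in 21 of 31, and in 27 when adjusted over the list alone, with Psmd1 at 0.52 ± 0.10. Lysosomal genes rose in 13 of 22 (16 when adjusted over the list alone), with Ctsd at 1.76 ± 0.36, and senescence-associated secretory genes in 11 of 17. Among the latter Mmp12, a macrophage elastase, was at least 44.9-fold higher by the same floor. Neuropeptide genes rose in 11 of 16, with Npy at 308 ± 59.4 against 60.3 ± 8.29 CPM, endothelial activation genes in 8 of 15 with Icam1 at 2.72 ± 0.43, and basement membrane genes in 7 of 16 with Sparc at 1.51 ± 0.25. The last 2 lists held 9 higher and 1 lower and 9 higher and 0 lower members when adjusted over the list alone. Heat shock genes rose in 3 of 11, led by Hspb1 (5.04 ± 1.02); 7 rose and 1 fell when adjusted over the list alone.

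Among the lower genes of the libraries labelled Thy1-Cre were 11 of 33 synaptic genes, with Stx1a at -1.02 ± 0.15 and Dlg4, the scaffold of the postsynaptic density, at -0.33 ± 0.08. Excitatory markers fell in 5 of 12 pan-excitatory genes, with Camk2a from 3596 ± 623 to 1923 ± 337 CPM, and in 4 of 12 upper-layer genes, with Lamp5 at -1.20 ± 0.20. Adjusted over the list alone these lists had 7 and 6 lower members, and the pan-excitatory list 1 higher. Myelin genes fell in 4 of 19, 6 when adjusted over the list alone, with Mbp, the myelin basic protein, from 2520 ± 163 to 1382 ± 162 CPM and Mal at -0.78 ± 0.16. Clock output genes fell in 3 of 15 (4 when adjusted over the list alone), among them Per3 (-1.48 ± 0.29) and Hlf (-1.21 ± 0.28). The haemoglobin gene Hba-a2, which has a near-identical copy and is uncertain, fell by 2.43 ± 0.61 on the log2 scale. The share of counts from haemoglobin genes was 0.0124% ± 0.00770 (SD, n = 5), against 0.0310% ± 0.0137 (n = 4) in controls. Plk5 and Myoc fell by 3.01 ± 0.40 and 2.90 ± 0.66.

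Over all genes 1866 were higher and 1345 lower in the libraries labelled Thy1-Cre, of which 982 and 396 differed at least 2-fold. Camera called 23 of 48 lists, with an adjusted p of 5.4e-18 for reactive astrocytes, and none at adjusted p = 0.0803 to 0.661 with an estimated correlation. Without replicate 1 or 4 of the controls or replicate 1, 3 or 4 of Thy1-Cre 1 or 2 of the 23 calls were lost (adjusted p = 0.0600 to 0.126), and in females alone that of the unfolded protein response (0.211). The libraries being all female, females alone (5 against 2 controls) gave 186 genes higher and 190 lower, and the 9 libraries fitted alone 1180 higher and 944 lower. In females alone 13 of the genes named for this comparison lost their call in edgeR's test, namely Mki67, Aurkb, Pcna, Hspb1, Dlg4 and Hba-a2 (adjusted p = 0.278, 0.242, 0.172, 0.120, 0.109 and 0.106) and Brap, Cd44, Ccl3, Ifitm3, Ctsd, Camk2a and Hlf (0.0555 to 0.0950).

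The libraries labelled Tie2-Cre, in which Cre acts in vascular endothelium, were compared with the same controls. No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 299 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0509 for Sorcs2, a sorting receptor named after its value was seen. DESeq2 called 4 genes higher and 3 lower, voom with quality weights 4 and 9, and edgeR on these 9 libraries alone 1 and 1. Without replicate 2 of the controls or replicate 1 of Tie2-Cre edgeR called 1 gene. Gfap had a mean of 264 ± 40.5 CPM (n = 5) against 191 ± 34.7 CPM (n = 4). C4b, uncertain as above, stood at 85.7 ± 23.8 CPM against 35.3 ± 15.2 CPM, above every control in 5 of 5 libraries, and did not pass the test (1.28 ± 0.29, adjusted p = 0.757 by edgeR's quasi-likelihood test). C4b was higher where Rps18 was lower. Controls 3 and 4, with Rps18 at 133 and 122 CPM, held 23.9 and 22.5 CPM of C4b. Controls 1 and 2, with 68.6 and 83.4 CPM, held 54.6 and 40.2 CPM. Replicate 1 of Tie2-Cre, with Rps18 at 66.8 CPM, held 54.8 CPM of C4b. The other Tie2-Cre libraries, with 2.67 to 3.99 CPM, held 78.7 to 121 CPM. The cause was not tested. C4b was the one complement gene of 12 that passed when adjusted over the list alone. Tek, whose promoter drives this Cre, changed by -0.29 ± 0.22. In simulated data of the same design 79.1% of 2-fold and 29.9% of 1.5-fold changes were recovered with a shared spread, and 62.7% and 19.4% with each group's own spread. These are changes in counts of the whole cortex, where a change confined to endothelial cells may be smaller.

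By camera 8 lists shifted with Tie2-Cre, 7 of them to higher values. These were complement (adjusted p = 0.00180), developmental transcription factors (0.00345), glucocorticoid targets (0.0258), blood (0.0258), synapse (0.0299), reactive astrocytes (0.0431) and hippocampal markers (0.0489), with oxidative phosphorylation lower (0.00497). With an estimated correlation adjusted p = 0.589 for the developmental factors and adjusted p = 0.885 with an estimated correlation for the others. None had a member past edgeR's test. The calls hung on single libraries. All 8 were lost without replicate 3 of the controls (adjusted p = 0.0512 to 0.535), 3, 4 and 2 of them without replicates 1, 2 and 4 of the controls (0.0530 to 0.416), and 2, 3, 2 and 4 without replicates 1, 3, 4 and 5 of Tie2-Cre (0.0576 to 0.333). The call of reactive astrocytes was lost in 6 of the 9 fits without 1 library and, like that of hippocampal markers, with RLE scaling (0.0533 and 0.0563). Replicate 3 of the controls had a mean log2 CPM of choroid plexus genes of 3.91, against -0.229 to 2.45 in the other controls, and of blood-brain barrier genes of 3.96, against 4.44 to 4.57. It held 20.1 CPM of Prl and 5.71 CPM of Gh, hormones of the pituitary, against up to 1.09 and 0.806 CPM in the other controls, while replicate 4 of Tie2-Cre held 19.3 and 7.64 CPM.

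At 10 months the libraries labelled Emx1-Cre, whose phenotype the labels call recovered, had 4 genes past edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, all higher. Blnk, an adaptor of B cell receptor signalling, rose from 6.97 ± 1.02 (n = 4) to 24.6 ± 9.06 CPM (n = 6), by 1.82 ± 0.26 (adjusted p = 0.00195). Atp2c2, a secretory pathway calcium pump, rose by 2.82 ± 0.44 and Trnp1, a nuclear protein of neural progenitors, by 1.05 ± 0.19. Slc6a5, the glycine transporter of inhibitory neurons, had 7490 counts against 3, a ratio with a counting interval from 588 to 8332, in 5 of 6 libraries. All 4 genes were also higher at 3 months, where 0.815 would be shared by independent lists. Gfap stood at 375 ± 174 CPM (n = 6) against 233 ± 8.75 CPM (n = 4) and did not pass the test (0.69 ± 0.38, adjusted p = 0.556 by edgeR's quasi-likelihood test).

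No list had a member past the test over all genes at 10 months, but camera called 11 lists, none of them with an estimated correlation (adjusted p = 0.826 for oxidative phosphorylation and adjusted p = 0.475 with an estimated correlation for the other 10). Immediate early genes were shifted lower (21 genes, median -0.79, adjusted p = 2.6e-07, and adjusted p = 0.475 with an estimated correlation), with Nr4a1 at 43.4 ± 17.5 against 142 ± 28.9 CPM, below every control in 6 of 6 libraries, and Egr1 at 157 ± 64.8 against 352 ± 26.8 CPM; 2 members were lower when adjusted over the list alone. Myelin genes were lower (median -0.45, adjusted p = 1.2e-06), as were fibroblast and meningeal markers (-0.62), blood-brain barrier genes (-0.25), mural markers (-0.42), class II antigen presentation (-0.97), thalamic markers (-0.21) and feedback genes of the RAS to MAP kinase pathway (-0.42). Among the latter were the phosphatase Dusp6, at 37.2 ± 11.1 against 63.5 ± 6.09 CPM, and Etv4, at 4.84 ± 1.59 against 8.10 ± 1.00 CPM. Proteasome subunits (median 0.18), interneuron markers (0.22) and oxidative phosphorylation (0.09) were shifted higher. Camera's adjusted p was between 4.0e-10 and 0.0370 for these lists. The mural call was lost without replicate 1 of the controls (adjusted p = 0.104), and the thalamic call without replicate 1 or 2 of the controls (0.111 and 0.0911) or replicate 2, 3 or 5 of Emx1-Cre (0.0571, 0.0502 and 0.0634).

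Replicate 6 of Emx1-Cre at 10 months held 184 CPM of Gfap, below the controls, where the other 5 held 296 to 665 CPM. Without it edgeR called 86 genes higher and 80 lower, and without replicate 1, 2, 3 or 4 of the controls 1, 1, 2 and 2 genes. The count was 0 on these 10 libraries alone and 0 in males alone, 69 higher and 32 lower with DESeq2, and 483 and 500 with voom and quality weights. Unadjusted p under 0.05 was reached by 1813 genes. The call of Blnk stood without any 1 library, that of Atp2c2 was lost without replicate 1 or 2 of the controls (adjusted p = 0.0851 and 0.0630), and those of Slc6a5 and Trnp1 without any 1 of the 4 controls (0.138 to 0.215 and 0.138 to 0.228). Trnp1 was also lost without replicate 1, 4 or 5 of Emx1-Cre (0.108, 0.122 and 0.0516), both genes with no filter (0.0564), and Slc6a5 with voom and quality weights (0.355).

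The change of the Emx1-Cre effect with age was tested as the effect at 10 months minus that at 3 months. Reactive astrocyte genes had a smaller effect at 10 months in 17 of 26, and in 20 when adjusted over the list alone. The difference was -2.78 ± 0.54 for Gfap, -7.20 ± 1.31 for Timp1 and -4.37 ± 0.84 for the filament Vim, with an adjusted p of 0.0082 each in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Disease-associated microglial genes had a smaller effect in 12 of 25 (21 when adjusted over the list alone), with Spp1, or osteopontin, at -5.80 ± 1.24 and Itgax at -3.09 ± 0.70. Complement followed in 7 of 12 (9 when adjusted over the list alone), with C4b, uncertain as above, at -2.08 ± 0.39, lysosomal genes in 6 of 22 (15) with Ctsd at -1.94 ± 0.47, class I antigen presentation in 3 of 13 (11) and interferon-stimulated genes in 2 of 34 (5), the values in parentheses being adjusted over the list alone. Icam1 and Edn1 differed by -3.00 ± 0.56 and -3.67 ± 0.68. Synaptic genes had a higher value at 10 months in 4 of 33 (8 when adjusted over the list alone), with Stx1a at 0.89 ± 0.20 and Gria4 at 0.85 ± 0.19.

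In all 409 genes had a higher and 633 a lower effect at 10 months than at 3 months. Of the genes higher at 3 months 627 were among the lower ones here, and of the genes lower at 3 months 400 were among the higher, where shared 3-month libraries add to both counts. Camera called 21 of 48 lists, from an adjusted p of 5.0e-16 for reactive astrocytes, and none at adjusted p = 0.302 to 0.809 with an estimated correlation. Without replicate 1 or 3 of the 3-month controls or replicate 1, 3 or 5 of Emx1-Cre at 3 months 1 or 2 of the 21 calls were lost (adjusted p = 0.0524 to 0.177), and in males alone 4 (0.278 to 0.943). The count was 3534 without replicate 6 of Emx1-Cre at 3 months. It fell below 1 part in 1.5 of its value in 14 other fits without 1 library, namely each of the 8 controls (306 to 550), replicates 1 and 5 of Emx1-Cre at 3 months (576 and 643) and replicates 3 to 6 of Emx1-Cre at 10 months (538 to 653). In males alone it was 15, and 10 of the genes named for this comparison lost their call (adjusted p = 0.0784 to 0.190 in edgeR's test).

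The libraries labelled Emx1-Cre and Thy1-Cre were compared directly at 3 months. Cholesterol synthesis genes were lower with Emx1-Cre in 12 of 17, and in 13 when adjusted over the list alone, among them Sqle, the squalene epoxidase, at 42.0 ± 12.5 (n = 6) against 74.0 ± 10.7 CPM (n = 5), Sc5d at -0.67 ± 0.13 and Idi1 at -0.75 ± 0.15. Genes of the unfolded protein response were lower in 6 of 17 (7 when adjusted over the list alone), with the chaperone Hsp90b1 at -0.53 ± 0.10. Txnip, a regulator of thioredoxin, was higher with Emx1-Cre by 2.88 ± 0.47 and Edn1 by 2.56 ± 0.45, while the hyaluronan synthase Has2 and the phosphodiesterase Gdpd3 were lower (-3.15 ± 0.54 and -3.91 ± 0.81). The histone gene H2bu2 was higher by 1.75 ± 0.23. Rpl29 was higher by 6.48 ± 1.67, but has near-identical copies and is uncertain. Glucocorticoid targets were higher in 3 of 10, with Tsc22d3 at 1.68 ± 0.31, and oxidative phosphorylation in 5 of 38.

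By edgeR's test 1404 genes were higher and 1432 lower with Emx1-Cre. This count depended on the other groups in the fit, since on these 11 libraries alone 13 were higher and 11 lower, and on single libraries: without Emx1-Cre replicate 1, 4 or 6 it was 1385, 1685 and 4878, and without Thy1-Cre replicate 3 or 5 it was 1562 and 1799. Of the genes named for this comparison Gdpd3, H2bu2, Hsp90b1 and Rpl29 passed on the 11 libraries alone. In simulated data with 200 changed genes, in which each group kept its own spread, 87 of 217 genes called for this comparison were unchanged ones (40.1%). Such a share depends on how many genes change, so it is not that of the real calls. Camera called cholesterol synthesis (adjusted p = 2.3e-07), oxidative phosphorylation (8.9e-05) and 7 other lists, none of them with an estimated correlation (adjusted p = 0.987 with an estimated correlation). The calls of cholesterol synthesis and oxidative phosphorylation stood without any 1 library, while up to 3 of the others were lost, as without replicate 5 of Emx1-Cre (0.0675 to 0.0694) or replicate 3 of Thy1-Cre (0.0653 to 0.107). Sex as a covariate lost the camera calls of the unfolded protein response and synapse (adjusted p = 0.0936 and 0.0751). In females alone camera lost both (0.281 and 0.430) and histone genes (0.230).

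Against the libraries labelled Tie2-Cre, those labelled Emx1-Cre had 4001 genes higher and 3628 lower, and those labelled Thy1-Cre 2200 higher and 1492 lower. Reactive astrocyte genes were higher in 24 of 26 and in 22 of 26, with Gfap at 3.00 ± 0.39 and 3.44 ± 0.40, and in the second comparison 1 was lower; adjusted over the list alone both had 24 higher and 1 lower. Cell cycle genes were higher with Thy1-Cre than with Tie2-Cre in 17 of 18 (18 when adjusted over the list alone), with Mki67 at 2.71 ± 0.63. Haemoglobin and other red cell genes were lower in 5 of 6 with Emx1-Cre and in 4 of 6 with Thy1-Cre, 5 in each when adjusted over the list alone, where Alas2, the haem synthesis enzyme, fell by 2.28 ± 0.53 and 2.05 ± 0.56. The haemoglobin share was 0.0489% ± 0.00559 (SD, n = 5) with Tie2-Cre. Camera's adjusted p for the blood list was 0.00833 and 6.2e-04, and adjusted p = 0.587 and 0.362 with an estimated correlation; the first call was lost in females alone (0.0965). In females alone the counts were 3489 and 399, and in males alone 3545 for Emx1-Cre. In females alone Mki67 lost its call (adjusted p = 0.271), as did Alas2 in both comparisons (0.0618 and 0.149).

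**Figure D3:**
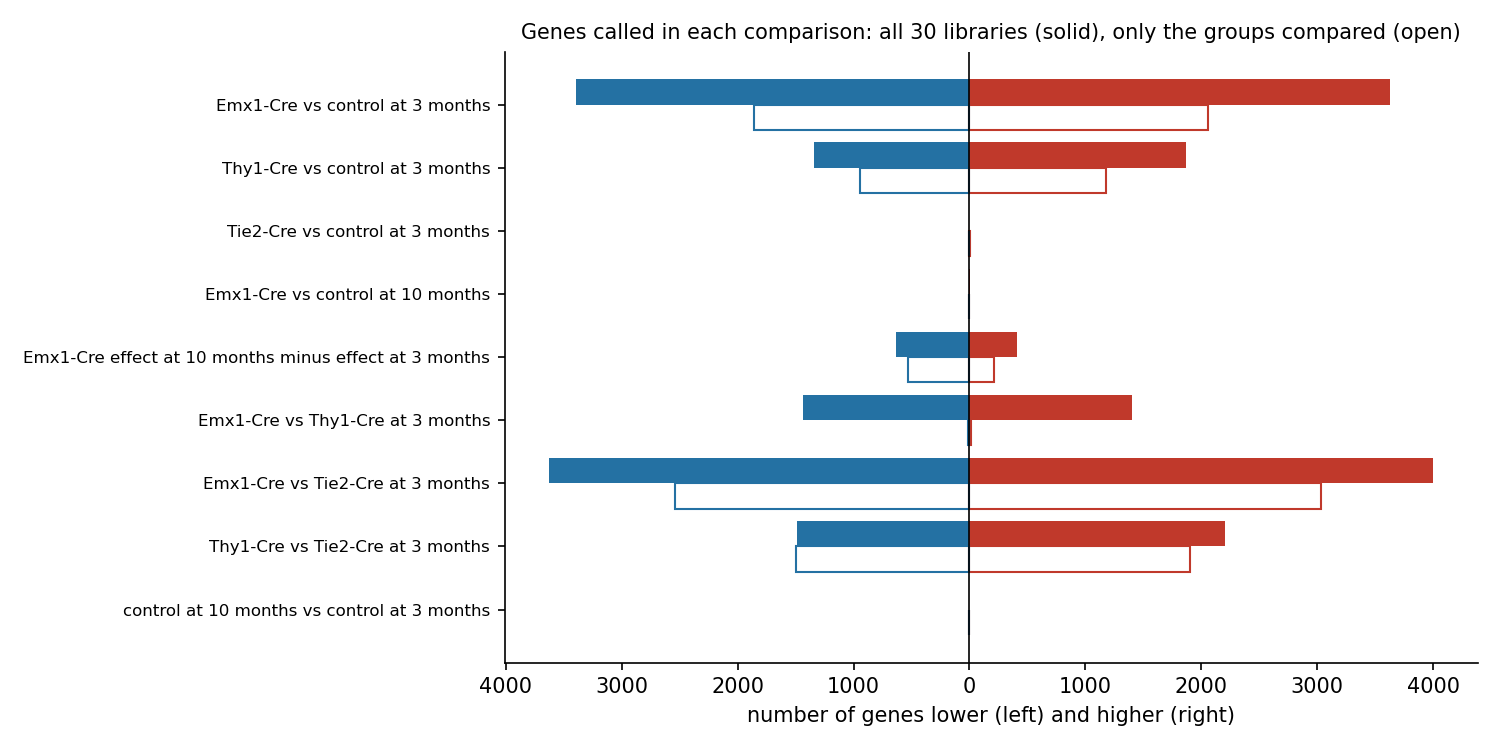
Genes higher (bars to the right) and lower (bars to the left) in each of the 9 comparisons, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Solid bars give the fit of all 30 libraries and open bars the fit of only the groups compared, both as numbers of genes on a linear axis. The fit of all libraries called 3628 and 3396 genes for Emx1-Cre against control at 3 months, 0 and 0 for Tie2-Cre and 4 and 0 for Emx1-Cre at 10 months.

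Age alone was compared in the controls, at 10 against 3 months. No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 447 at an unadjusted p under 0.05 and a smallest adjusted p of 0.122, which belonged to C4b, uncertain as above. C4b stood at 115 ± 25.8 CPM (n = 4) at 10 months against 35.3 ± 15.2 CPM (n = 4), higher in 4 of 4. Replicate 2 of the 10-month controls, with Rps18 at 3.61 CPM, held the most C4b (151 CPM). Replicates 1, 3 and 4, with Rps18 at 62.4 to 66.1 CPM, held 89.1 to 111 CPM. The 3-month controls nearest in Rps18 (68.6 and 83.4 CPM) held 54.6 and 40.2 CPM of C4b. DESeq2 called 7 genes higher and 0 lower, voom 6 and 1, and edgeR 1 without replicate 1 or 3 of the 3-month controls. Camera called 12 lists, for which adjusted p = 0.962 to 0.967 with an estimated correlation. Oxidative phosphorylation (38 genes, median -0.18, adjusted p = 4.9e-15, and adjusted p = 0.962 with an estimated correlation) and proteasome genes (31 genes, median -0.12, adjusted p = 7.8e-05, 0.967 with an estimated correlation and 0.850 in males alone) were shifted lower and complement genes higher (0.00176, 1 member of 12 higher when adjusted over the list alone). Class II antigen presentation was shifted higher (0.00403), a call lost without replicate 1 of the 10-month controls (0.09297). Up to 5 of the 12 calls were lost without 1 library, 5 of them without replicate 3 of the 10-month controls (0.0635 to 0.288). The ages were not paired, and which litters or batches the mice came from is not given in the sources used here.

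Across genes, which are not independent replicates, the effects of Emx1-Cre and Thy1-Cre at 3 months correlated with r = 0.763, and 75.8% of genes had the same sign. Since both used the same 4 controls, unchanged groups simulated against these controls gave r = 0.604 and 63.7%. The covariance was 0.707, against 0.100 in the simulation, a difference of 0.607, and with the controls split 2 and 2 it was 0.630, with r = 0.575. The 2 comparisons shared 1406 higher and 926 lower genes, where independent lists would share 380 and 257, and 5 genes went opposite ways. For Emx1-Cre and Tie2-Cre the covariance was 0.155 against 0.0969 simulated, and 0.0741 with the controls split. Their r was 0.360 against 0.619 simulated, and 55.7% of genes had the same sign against 66.8%. For Thy1-Cre and Tie2-Cre the covariance was 0.127 against 0.0968, and 0.0442 with the controls split, with r at 0.316 against 0.617 and 58.3% against 67.2% of genes of the same sign. These lower values of r and of the sign share say nothing against similarity. The simulated groups had no effects of their own, while those of Emx1-Cre and Thy1-Cre widen the spread and set the signs. The effects of Emx1-Cre at 3 and 10 months, which share no library, correlated across genes with r = 0.353.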

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

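The tests of Brap other than that of scaling and those of Rps18 and Rps3a family counts were chosen only after the result was seen. For 11 values given per library, 66 groups in all, the highest and lowest library were set against the rest, and 5 values stood out, where chance gives about 1 in 20 groups.

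In the libraries labelled Emx1-Cre at 3 months, replicate 6 stood apart on the first principal component, at -1.58 against 70.2 to 88.5 in the other 5, and in the mean log2 CPM of reactive astrocyte genes, at 2.96 against 4.84 to 5.46. Replicate 2 of the 3-month controls had 243 CPM of Gfap against 168 to 179 in the others. The mean log2 CPM of myelin genes was 5.97 in replicate 3 of the 10-month controls against 6.34 to 6.40, and 5.08 in replicate 2 of Emx1-Cre at 10 months against 5.82 to 6.13. No technical or biological explanation was tested for these values.

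Effects differed between groups in 4 tested contrasts. The Emx1-Cre effect differed between ages for 1042 genes, Emx1-Cre from Thy1-Cre for 2836 genes, Emx1-Cre from Tie2-Cre for 7629 genes and Thy1-Cre from Tie2-Cre for 3692 genes. Regroupings of the same libraries tested whether such counts arise by chance. Chance is argued against where only the real grouping was as large (1 of 100). This held for Emx1-Cre against control at 3 months (7024 genes, highest other 6659) and Thy1-Cre against control (3211, highest other 2910). It held also for Emx1-Cre against Tie2-Cre (7629, highest other 6077) and Thy1-Cre against Tie2-Cre (3692, highest other 1306). A share of 1 of 100 is the smallest that 100 groupings can give, and 9 comparisons were made. Not all possible groupings (126 to 462 in these comparisons) were drawn. The regroupings also cannot part the Cre label from other differences between the groups, such as the sex of the Thy1-Cre mice or Rps18. For the change with age the regroupings cannot decide. Labels were exchanged within each age, which undoes the effect at each age and not only the difference between ages. The real grouping called 1042 genes, and 4 of 100 groupings drawn from 44100 were as large, 1 fewer than the set limit. The count ran from 306 to 3534 without 1 library. The highest other grouping called 2964. At 3 months it exchanged all 4 controls with replicates 1, 3, 4 and 5 of Emx1-Cre, so it kept much of that difference with its sign turned.

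Chance cannot be excluded for Emx1-Cre against Thy1-Cre (2836 genes, 5 of 100 groupings as large, highest other 4431) and Emx1-Cre against control at 10 months (4 genes, 6 of 100, highest other 84). For Tie2-Cre against control and for age in the controls the real count was 0, so that every grouping is as large (100 of 100 and 35 of 35, highest others 4 and 1) and the regroupings say nothing about chance. The highest other grouping at 10 months set replicates 1, 3, 4 and 5 of Emx1-Cre against the 4 controls with replicates 2 and 6 of Emx1-Cre, and its 84 genes, many times the real count, point to a structure of the samples within the Emx1-Cre libraries. The highest other grouping of Emx1-Cre against Thy1-Cre exchanged replicate 6 of Emx1-Cre with replicate 1 of Thy1-Cre.

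Brap counts were higher in the libraries labelled Emx1-Cre and Thy1-Cre at 3 months, and changed by 0.10 ± 0.12 (SE) in those labelled Tie2-Cre. For scaling between libraries the planned test cannot decide. Library totals alone gave Brap a log2 change of 0.618 ± 0.112 (SE) with Emx1-Cre and 0.392 ± 0.115 with Thy1-Cre. The TMM factors were so alike (means 1.005 in controls and 0.994 with Emx1-Cre) that leaving them out moved little. A scaling factor moves all genes of a library alike, however, and the median gene changed by 0.0076 and -3.93e-05. Set beside Brap only afterwards, these medians argue against scaling as the source of its rise over other genes. Reads from exons outside the deleted part, or a missing deletion, were predicted to leave counts at or below the controls. Brap rose by 0.636 ± 0.119 (SE) with Emx1-Cre. This cannot decide the question, since the value tested is the rise to be explained. Whether the deletion took place cannot be read from 1 value per gene. A second floxed allele, which the controls lack, is argued against as the whole source, since Brap was higher by 0.535 ± 0.110 (SE) with Emx1-Cre than with Tie2-Cre, where the labels give the same alleles, and by 0.287 ± 0.114 with Thy1-Cre (adjusted p = 0.0737 in edgeR's test). Reactive glia or immune cells with more Brap mRNA are argued against as the whole source, if their Brap followed their markers alike at both ages. At 10 months Brap was 19.2 ± 4.52 CPM (SE) above the controls, 56.1% of its excess at 3 months, though it did not pass the test over all genes (adjusted p = 0.251). The summed CPM of 5 glial and immune lists kept 2.30% to 13.8% of its excess, which would leave at most 4.73 CPM for Brap. What was left ranged from 551 ± 184 CPM (SE) for lysosomal genes to 13.5 ± 13.3 CPM for interferon-stimulated genes. The latter, and the 153 ± 212 CPM of disease-associated microglia, cannot be told from the control level. A part from such cells and an effect of the deletion on Brap transcription stay open, the latter as untested.

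Replicate 6 of Emx1-Cre at 10 months lay nearer to the controls of its age than the other Emx1-Cre libraries did. Of the 4 genes called at that age, Blnk (10.2 against 6.02 to 8.30 CPM) and Trnp1 (110 against 86.5 to 104 CPM) lay above every control in it. Atp2c2 and Slc6a5 lay within the control range. Over the 3211 genes called for Thy1-Cre the mean signed deviation of this library was -0.0567. That is below the 4 controls of its age (-0.0282 to 0.0459) and the other 5 Emx1-Cre libraries (0.138 to 0.380). A swap with a control of that age is argued against, since 0 of the 4 controls reached the lowest of these 5. A wrong genotype label or absent recombination may explain the value, and so may a mouse without the phenotype, and these cannot be told apart since no count of the deleted exons is given.

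Rps18 stood under 10 CPM in all 11 Emx1-Cre and Thy1-Cre libraries of 3 months and over 50 CPM in the 4 controls of that age. An effect of the Brap deletion is argued against as the whole source, since 3 of the 6 groups held libraries at both levels, a control group among them. Reads shared between near-identical copies may explain the steps of Rps18, Rps3a2 and Rps3a3. The summed CPM of the 4 genes of the Rps18 family differed by 0.225 on the log2 scale (156 ± 35.7 against 133 ± 16.7 CPM). For Rpl29 shared reads met the test set beforehand, a difference of the sum under 1 on the log2 scale. The sum of the 12 genes of its family differed by -0.682 between Thy1-Cre and control (94.1 ± 15.6 against 151 ± 31.6 CPM). The 10-month values of this family were looked at only afterwards, and they argue against shared reads as the whole source. At 10 months this sum was 104 to 121 CPM in the libraries with Rpl29 at 66.7 to 79.2 CPM. It was 74.5 to 85.0 CPM in those with Rpl29 at 1.02 to 1.60 CPM. For Rps3a2 and Rps3a3 the 10-month libraries were used, since these genes held 88.5% or more of the sum of their family in 2 of them. The sum was 235 CPM on average in these 2 libraries and 244 CPM in the 3 with the genes under 1 CPM, a log2 difference of 0.0556, where the loss of a transcript would have lowered it. Over all libraries Rps18 lay at separate levels, 2.67 to 6.62, 56.4 to 83.4 and 122 to 133 CPM. A variant carried with the strain of the mice was not tested. Rps18 parted the 3-month Emx1-Cre and Thy1-Cre libraries from their controls. Such a variant could thus not be told apart there from the deletion, for Rps18 or for genes inherited with it.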

How the results depend on the processing

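Fits of 1 sex and fits without replicate 6 of Emx1-Cre at 10 months were chosen only after the result was seen; the other alternatives were planned. The RLE scaling, the stricter filter and sex as a covariate kept every count of called genes within 1.5 times its value, and no scaling reversed a named gene. Of 114 named gene calls 60 held under every alternative run, and 4 were lost without 1 library. The cause of each change below was not tested, except that fits of fewer libraries have fewer samples.

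With only the groups compared, 3909 genes were called for Emx1-Cre against control at 3 months (3860 of them called the same way in the fit of all libraries), 2124 for Thy1-Cre, 2 for Tie2-Cre, 0 for Emx1-Cre at 10 months and 24 for Emx1-Cre against Thy1-Cre. No filter gave 1 gene for Tie2-Cre, 2 for Emx1-Cre at 10 months, 460 for the change with age and 1884 for Emx1-Cre against Thy1-Cre. DESeq2 called 7 genes for Tie2-Cre, 101 for Emx1-Cre at 10 months, 1837 for the change with age and 7 for age in controls. Voom with quality weights called 13, 983, 3898 and 7 genes in these, and 1407 for Emx1-Cre against Thy1-Cre. With replicate numbers as a replicate block 99 genes were called at 10 months, where the share of higher genes moved by -53.5 points, and 1774 for the change with age, where it moved by 13.5 points; age in controls has no value with this block, since it is confounded with age.

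Females alone gave 3296 genes for Emx1-Cre against control at 3 months, 376 for Thy1-Cre, 3 for Tie2-Cre, 1640 for Emx1-Cre against Thy1-Cre, 3489 for Emx1-Cre against Tie2-Cre and 399 for Thy1-Cre against Tie2-Cre. Males alone gave 2294 for Emx1-Cre at 3 months, 0 at 10 months, 15 for the change with age and 3545 for Emx1-Cre against Tie2-Cre. Without replicate 6 of Emx1-Cre at 10 months, the groups compared gave 646 genes and voom with quality weights 1878.

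Leaving out 1 library gave 5544 to 8261 genes for Emx1-Cre at 3 months, 2153 to 3595 for Thy1-Cre, 0 to 1 for Tie2-Cre, 1 to 166 for Emx1-Cre at 10 months, 306 to 3534 for the change with age, 1385 to 4878 for Emx1-Cre against Thy1-Cre, 6623 to 8870 for Emx1-Cre against Tie2-Cre, 2705 to 3976 for Thy1-Cre against Tie2-Cre and 0 to 1 for age in controls.

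Of 150 list calls by camera 0 held with an estimated correlation. Fry made 96 list calls, 84 of them the same way. In males alone 2 lists reversed: hippocampal markers with Tie2-Cre (adjusted p = 0.942 by camera) and choroid plexus genes with age in controls (0.00828). With the controls split 2 and 2, r between the Emx1-Cre and Thy1-Cre effects was 0.575. In simulated data 10.4% to 50.7% of 1.5-fold changes were recovered with a shared spread and 7.46% to 37.3% with each group's own spread; depth was not varied.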

Other observations

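The fits without replicate 6 of Emx1-Cre at 10 months were chosen only after the result was seen. Without it a fit of the groups compared called 331 genes higher and 315 lower, 646 in all, and voom with quality weights 944 and 934, so the small count at that age may rest in part on that library (4 genes with it, 166 without it in the fit of all libraries).

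Simulated data with 200 changed genes were also drawn with each group's own spread. There 14.3% of the genes called for Emx1-Cre against control at 3 months and 13.6% of those called for Thy1-Cre were unchanged ones. With a shared spread the shares were 4.17% and 1.29%. Such shares depend on how many genes change, so they are not those of the real calls.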
